A study of Capra hircus with 8 samples.

How the data were processed

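RNA sequencing libraries of 8 samples of goat intramuscular preadipocytes (so named in the labels' source and cell type, while the sample titles say adipocytes) were grouped by the labels into si-CPT1B (n = 4) and NC (n = 4), and each column of the deposited tables was matched to its sample by the column name in the sample's description. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, poly(A) RNA was selected and fragmented, and the second cDNA strand was marked with dUTP and removed with UDG, which keeps the strand of each transcript. Per the submitters' processing notes, fastp, HISAT2, SAMtools and HTSeq were used. Their versions, the genome build, the annotation release and the strand setting of the counting are not given in the sources used here.

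The authors deposited raw counts of reads per Ensembl gene for 27271 genes, followed by 5 summary entries of HTSeq that name no gene. Those 5 entries held all but 0.705% to 0.771% of the reads of each library: the no-feature entry alone held 90.6% to 93.6%, reads not aligned 1.24% to 3.66%, reads aligned to several places 3.24% to 3.86% and reads of low alignment quality 1.11% to 1.31%. They were kept out of library sizes and tests. Of the 27271 genes, 14311 (52.5%) had 0 reads in every library, 2825 had reads in all 8, and 16603 had a symbol. The deposited FPKM values were made by the authors from those counts: dividing count by FPKM and by the library's summed gene counts returned a whole-number gene length, within 0.01%, for 100% of the 54464 values above 0. The FPKM therefore add no information beyond the counts and a length. No column was left unused. A count of 0 was taken to allow 3 reads. That floor covers counting error only, since the reads carry no molecular identifiers. The 97.1% intervals run between the extreme differences of single libraries of the groups, so they reflect the spread between libraries.

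Because the library kit marks strand and the strand setting is unknown, reads counted on a gene may be reads of that gene or of a gene overlapping it on the other strand, and values are given as reads counted on a gene. This limits every value printed, for genes with and without another gene within 1 kb.

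Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test with robust dispersion, Benjamini-Hochberg adjustment, threshold 0.05), with the group as the only term. The filter left 1636 genes, which held 94.1% of gene reads, with a biological coefficient of variation of 0.21. Mean ± SD values and sums per library are TMM-scaled CPM, relative to the reads on the 1636 tested genes, while the bound on CPT1B is relative to all reads on genes. Gene lists with at least 5 tested members were tested with camera on voom values (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. Of 738 distinct listed genes in the table, 132 were tested. Reads summed over each list were tested with edgeR, which was added after seeing the data. Single values were compared with two-sided exact permutation tests.

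Genes were named by a rule: the carnitine palmitoyltransferases; the 12 largest changes each way, and the 4 smallest p each way, among genes past the threshold whose groups did not overlap, with a symbol and a mean of at least 1 CPM; and for each list up to 4 members past the threshold or, with none, the member with the smallest p. The result of 1 gene under this rule is not reported here. Other members of the lists that are named, and genes named in the closing part, were chosen after their values were seen.

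On simulated counts with the means and library sizes of these 1636 genes and 200 genes changed, the edgeR steps recovered 17.1% of 1.5-fold, 57.8% of 2-fold and 92.4% of 4-fold changes, with 3 false calls among 113. These shares hold for 200 changed genes. With fewer, the Benjamini-Hochberg adjustment asks for a smaller p and recovers less. Alternatives covered the scaling, the filter, DESeq2 1.42.0, limma with library quality weights, limma on log2 FPKM with 2 pseudocounts (1 and 0.1), the replicate number as a block, each library left out and stricter thresholds. Scaling to abundant mRNAs (50 housekeeping genes listed, 32 of them in the table, with 16 ribosomal protein genes, 48 in all) and scaling to all reads were added after seeing the data. Replicates of a group were compared pairwise by chi-square tests over genes, and no pair agreed within sampling noise (chi-square per degree of freedom 2.64 to 10.7).

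A RefSeq gene table of assembly ARS1.2 was used only for which genes neighbour each other and for the length of each locus. Of 14733 nuclear genes with a symbol of their own, 13049 (88.6%) matched. Of all entries with a symbol, repeated symbols included, the share was 78.6%. The denominator without repeated symbols was chosen after that lower share was seen. No coordinates are printed, since the deposited tables name no build.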

Results

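Poly(A) RNA of cultured goat intramuscular preadipocytes, the fibroblast-like precursors of the fat cells that lie between muscle fibres, was sequenced after transfection with small interfering RNA against CPT1B (si-CPT1B, n = 4) or with a negative control interfering RNA (NC, n = 4). CPT1B is the muscle form of carnitine palmitoyltransferase 1, which loads long-chain fatty acids for entry into mitochondria. The series title names lipid deposition and p38 MAPK signalling as the study's subject, so the comparison asks which transcripts differ once CPT1B is targeted. The deposited table held 39276220 to 46146839 reads per library, of which 295349 to 352184 were counted on genes. The share of reads counted on genes was 0.714% ± 0.0103 in si-CPT1B and 0.764% ± 0.00938 in NC libraries (SD, n = 4 each, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). Every value here is therefore a number of reads counted on a gene in a shallow table. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples.

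The targeted gene itself could not be measured. CPT1B (ENSCHIG00000023593) had 0 reads in all 8 libraries, which allows up to 8.52 to 10.2 CPM in a library (CPM, counts scaled to the reads on genes), for counting error only. That bound is on the reads counted on CPT1B, and bounds its transcript only if the counting took the transcript's own strand. Its relatives were close to the same floor: 8 reads in total over the 8 libraries were counted on CPT1A, the liver form, 1 on CPT1C, the brain form, and 1 on CPT2, which acts at the inner mitochondrial membrane. A knockdown of CPT1B could not be seen in this table, which offers no check of the labels.

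Few single genes differed between the groups. Of 1636 genes with enough reads to test, 1 was higher and 4 were lower in si-CPT1B by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Reads on EIF4G2, a translation initiation factor related to eIF4G, fell to 33.4 ± 11.2 CPM in si-CPT1B from 117 ± 30.0 CPM in NC (SD, n = 4 each), a log2 fold change of -1.78 ± 0.35 (SE, edgeR adjusted p = 0.0184). Reads on RIC3, a chaperone of nicotinic acetylcholine receptors, fell to 2092 ± 93.9 from 2950 ± 195 CPM, a log2 fold change of -0.50 ± 0.095 (SE, edgeR adjusted p = 0.0184). RIC3 lies within 1 kb of TUB in RefSeq, and the strand of the counted reads is not known. In both genes all 4 si-CPT1B libraries lay below all 4 NC libraries.

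The other 3 genes carry no symbol in the deposited tables, and they were singled out after their values were seen. ENSCHIG00000023501 rose to 9898 ± 1603 from 5648 ± 888 CPM (log2 fold change 0.81 ± 0.13 SE, edgeR adjusted p = 0.00523). ENSCHIG00000014215 fell to 108 ± 13.1 from 240 ± 44.0 CPM (log2 fold change -1.14, edgeR adjusted p = 0.0177). ENSCHIG00000011416 had 0, 2, 2 and 5 reads in the si-CPT1B libraries and 26, 20, 37 and 12 in the NC libraries (log2 fold change -3.29, edgeR adjusted p = 0.0177). Without any adjustment 194 genes had p under 0.05, 81 of them higher and 113 lower, where chance gives 81.8.

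The number of lower genes depended on single libraries. It was 15 without si-CPT1B replicate 1, 0 without si-CPT1B replicates 2 or 3 or NC replicates 1, 2 or 3, 1 without si-CPT1B replicate 4 and 3 without NC replicate 4. Fewer reads on RIC3 and EIF4G2 are relative to the other genes. Libraries were also scaled to a set of abundant mRNAs, a setting chosen after seeing the data and after some members had been seen low. Such a scaling raises every log2 fold change, so a lower call lost under it is no independent check. The median log2 fold change of all genes moved to 0.70, that of RIC3 to 0.21 and that of EIF4G2 to -1.13. EIF4G2 belongs to that set, and both calls were lost (edgeR adjusted p = 0.636 for RIC3 and 0.0775 for EIF4G2). ENSCHIG00000014215 moved to -0.44 and lost its call too (edgeR adjusted p = 0.36).

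**Figure D1:**
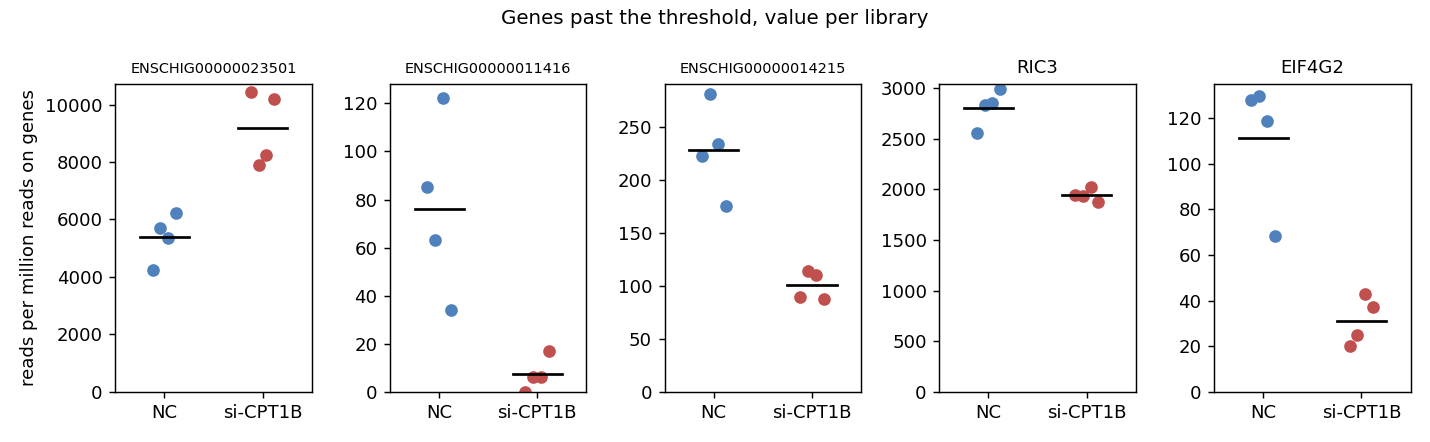
CPM, counts scaled to the reads on genes without a further factor, for the 5 genes that passed the test; each point is 1 library (4 NC, 4 si-CPT1B) and each line is the group mean. The groups do not overlap in any of the 5 genes. With libraries scaled to abundant mRNAs, a set chosen after some members had been seen low, the median of all genes moved to 0.70. Lower calls lost under that scaling are no independent check. RIC3 then had a log2 fold change of 0.21 and did not pass (edgeR adjusted p = 0.636). EIF4G2 (edgeR adjusted p = 0.0775) and ENSCHIG00000014215 (0.36) did not pass either.

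Among 33 gene lists fixed before the data were examined, 9 had the 5 tested members needed for a set test, and 3 of these were lower in si-CPT1B by camera with a preset correlation. With an estimated correlation 0 lists passed, and by fry 0. Of the 35 splits of the 8 libraries into 4 and 4, 8 gave at least 3 lists, the real one included. Extracellular matrix genes had the smallest p: 22 of 23 tested members had negative log2 fold changes, with a median of -0.54 (camera adjusted p = 2.71e-06, and adjusted p = 0.378 with an estimated correlation). No member was past the threshold over all genes tested, while 4 were lower when adjusted over the list alone. The fibrillar collagen gene COL1A2 had 383 ± 134 CPM in si-CPT1B and 683 ± 110 CPM in NC (SD, n = 4 each; log2 fold change -0.83, edgeR adjusted p = 0.114). FN1, which encodes fibronectin and held 31.9% of the list's reads, had a log2 fold change of -0.99 (edgeR adjusted p = 0.29), COL5A2 one of -0.66 and THBS2 one of -0.80. COL1A1, the partner chain of COL1A2, had -0.10 and COL8A1 had 0.59.

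All 11 tested genes of cytosolic ribosomal proteins had negative log2 fold changes, with a median of -1.07 (camera adjusted p = 0.000185, and adjusted p = 0.214 with an estimated correlation). None passed over all genes and 2 were lower adjusted over the list alone. RPL31 had 42.5 ± 14.7 CPM in si-CPT1B and 99.5 ± 20.1 in NC (SD, n = 4 each), RPS18 a log2 fold change of -1.17 and RPL37 one of -1.26. Skeletal muscle markers were the third list, at camera adjusted p = 0.0488, and adjusted p = 0.378 with an estimated correlation. Of its 6 tested members 5 were negative, among them the embryonic myosin MYH3 with 220 ± 97.6 against 390 ± 92.0 CPM and the intermediate filament gene DES at -0.74, and 1 was lower adjusted over the list alone. The call for muscle markers ended in 12 of 20 alternatives, with adjusted p of 0.0583 to 0.383 there. Among these were the fits without si-CPT1B replicate 1 (adjusted p = 0.118) and without NC replicate 3 (adjusted p = 0.0647).

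The matrix shift was strongest in si-CPT1B replicate 1. Summed extracellular matrix reads were 4055 CPM in si-CPT1B replicate 1, 7879 to 9281 CPM in the other si-CPT1B libraries and 8512 to 13170 CPM in NC. Reads of the abundant mRNAs used for scaling, a list written after some members had been seen low, were 1909 CPM, 3193 to 4077 CPM and 3658 to 5657 CPM in the same order, with 2.12 to 2.51 matrix reads for each in every library. Genes with any read numbered 5791 to 6828 in si-CPT1B and 6908 to 7350 in NC libraries (two-sided exact permutation p = 0.0286, and 0.0571 without si-CPT1B replicate 1). Under the scaling to abundant mRNAs, which moved the median of all genes to 0.70 and includes the ribosomal proteins, the list medians were 0.08 for extracellular matrix, -0.42 for ribosomal proteins and -0.14 for skeletal muscle markers.

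When the reads of all members of a list were summed and tested as 1 feature by edgeR, 4 of the 33 lists passed, all lower in si-CPT1B. Cytokine and NF-kB response genes fell by 0.61 on the log2 scale (edgeR adjusted p = 0.0163), led by the complement gene C3 with 212 ± 79.8 against 391 ± 92.4 CPM (SD, n = 4 each). C3 is not itself a cytokine. It was lower adjusted over the list alone, whereas NFKB1 had a log2 fold change of -0.15. Ribosomal protein reads fell by 0.79 on the log2 scale (edgeR adjusted p = 0.0169). The sum of ATF4 and unfolded protein response genes fell by 0.53 (edgeR adjusted p = 0.0234), with HSP90B1 and CALR, both chaperones of the endoplasmic reticulum, at log2 fold changes of -0.51 and -0.54. This list did not pass the set test (camera adjusted p = 0.195, and adjusted p = 0.378 with an estimated correlation). It passed at a mean of at least 5 CPM (camera adjusted p = 0.00809), without NC replicate 1 (0.0204) and without NC replicate 4 (0.0161), where an estimated correlation gave adjusted p of 0.18 to 0.314. TGF-beta and BMP signalling genes fell by 0.53 (edgeR adjusted p = 0.0308), with TGFBI at -0.91 and LTBP2 at -0.30. The summed extracellular matrix reads did not pass (log2 fold change -0.57, edgeR adjusted p = 0.11), nor did skeletal muscle markers (-0.61, edgeR adjusted p = 0.0562). These sums were added after seeing the data. The abundant mRNAs used for scaling were chosen after some members had been seen low. Scaling to them raises every log2 fold change, so lower calls lost there are no independent check. Under the scaling to abundant mRNAs, which moved the median of all genes to 0.70 and includes the ribosomal proteins, 0 of the 33 sums passed: the log2 fold changes of these 4 were 0.07, -0.18, 0.17 and 0.18 in the same order (edgeR adjusted p = 0.894, 0.7, 0.7 and 0.7). With libraries scaled to all reads 9 sums passed, all lower.

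**Figure D2:**
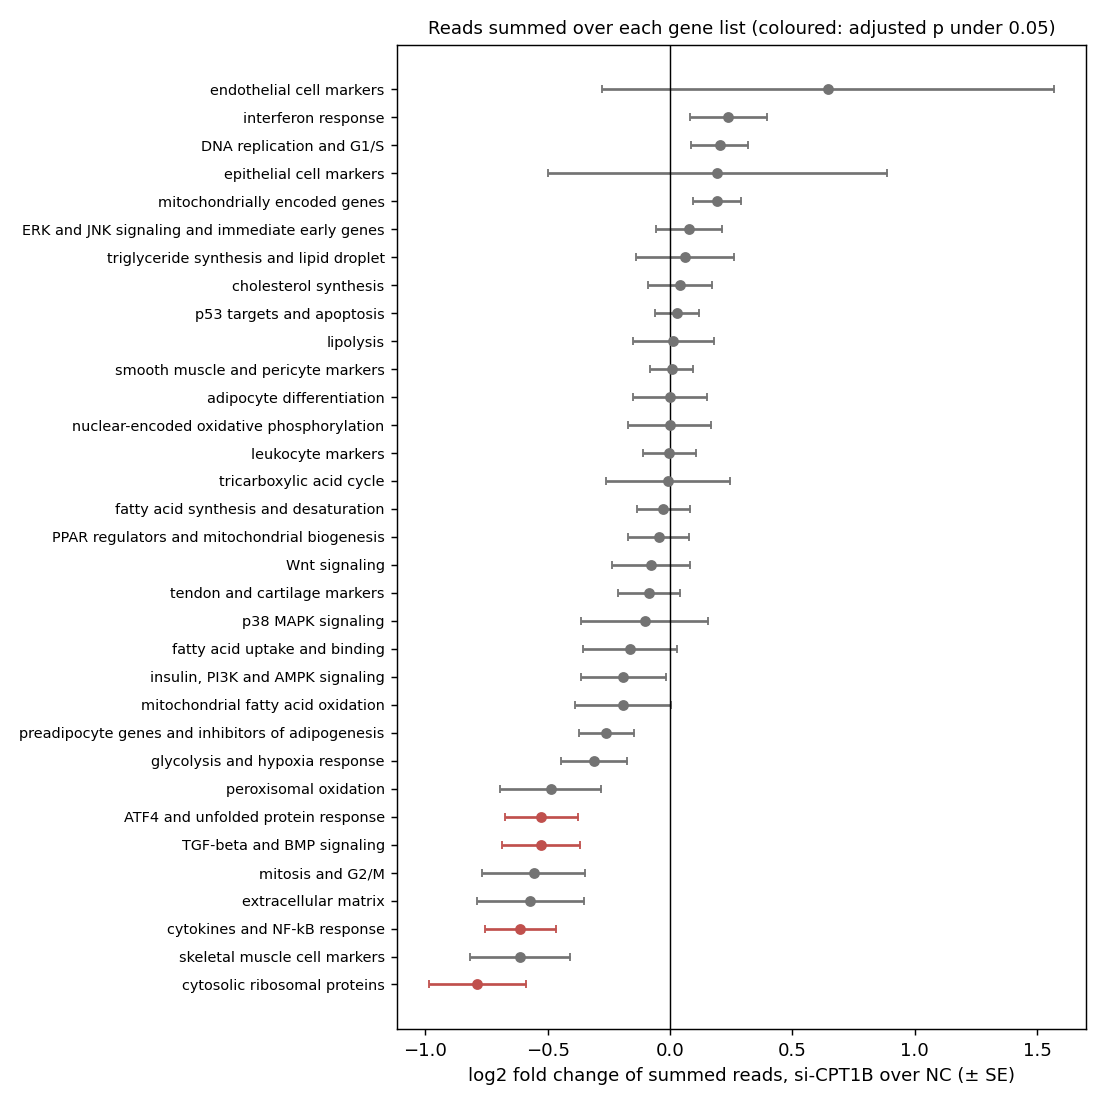
Log2 fold change, si-CPT1B over NC, of the reads summed over each of the 33 gene lists, with bars of 1 standard error from edgeR (4 libraries per group); coloured points had an adjusted p under 0.05. The 4 coloured lists lie between -0.79 and -0.53 with TMM scaling. Scaling to abundant mRNAs, a set chosen after some members had been seen low, moved the median of all genes to 0.70. The ribosomal protein sum, whose genes are in that set, was then -0.18, the other 3 were 0.07 to 0.18 and none passed. Such a scaling raises every log2 fold change, so this loss is no independent check.

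Lipid metabolism, the study's subject, was close to the floor of the table. PPARG, the master regulator of adipogenesis, the lipase gene LPL, the fatty acid transporter CD36 and leptin (LEP) had 0 reads in every library, FABP4 had 4 reads in total and ADIPOQ had 2. Such counts do not show that the genes were silent, since the strand of the counted reads is not known. Of the housekeeping genes used for scaling, S100A6 also had 0 reads and TUBA1B 36 in total, while MYH9 had the most, 1680. Adipocyte differentiation genes had 3 tested members and a list sum that differed by a log2 of -0.00080 (edgeR adjusted p = 0.996). They were CEBPD, with 148 ± 48.2 CPM in si-CPT1B and 184 ± 27.1 in NC, KLF9 at a log2 fold change of -0.02 and CEBPB at 0.20. CEBPD lies within 1 kb of SPIDR in RefSeq, so reads counted on either gene may belong to the other. SPIDR had 42713 reads in total, 1909 to 6771 per library, against 398 in total on CEBPD. Triglyceride synthesis and lipid droplet genes summed to a log2 fold change of 0.06, with CIDEB, a lipid droplet protein, at 63.2 ± 10.8 and 52.6 ± 16.5 CPM. Lipolysis genes gave 0.01, with PNPLA2, the first lipase of triglyceride breakdown, at -0.02 and PDE3B at 0.31. Fatty acid synthesis gave -0.03, 82.6% of it TECR reads, with SLC25A1, the mitochondrial citrate carrier, at 106 ± 32.1 against 82.6 ± 27.9 CPM (log2 fold change 0.36), a median over its 3 tested members of -0.03 and a mean of 0.09. Cholesterol synthesis gave 0.04 with MVD at 0.42, and fatty acid uptake and binding gave -0.16 with LRP1 at -0.18.

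Fatty acid oxidation was as thinly covered. Mitochondrial oxidation genes held 62 to 113 reads per library, 58.8% of them on ETFDH, and their sum had a log2 fold change of -0.19 (edgeR adjusted p = 0.747). ACADVL, the first dehydrogenase for very long chains, had 36.9 ± 18.3 CPM in si-CPT1B and 34.2 ± 14.1 in NC (SD, n = 4 each). Peroxisomal oxidation genes gave -0.49 (edgeR adjusted p = 0.11), mostly reads on the thioesterase gene ACOT8 (log2 fold change -0.35). Genes of preadipocytes and inhibitors of adipogenesis gave -0.26 (edgeR adjusted p = 0.11), with 73.7% of the reads on ENG. The fibroblast receptor gene PDGFRA had 18.4 ± 18.3 against 47.0 ± 21.3 CPM. PPAR regulators and mitochondrial biogenesis genes did not pass (camera adjusted p = 0.752), and POLG, the mitochondrial DNA polymerase, had a log2 fold change of -0.27.

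For p38 MAPK signalling, 30 of the 31 listed genes were in the table and all 30 had a mean under 10 reads. MAPK14, which encodes p38 alpha, had 1 read in all 8 libraries together, MAPK11 had 5, MAPK12 had 4, MAPK13 had 4 and the upstream kinase gene MAP2K3 had 10. As the strand of the counted reads is not known, these counts do not show whether the genes were expressed. GADD45G, the only member tested, had 39.7 ± 22.6 CPM in si-CPT1B and 27.8 ± 14.0 in NC (log2 fold change 0.52, edgeR adjusted p = 0.797). The list sum had a log2 fold change of -0.10 ± 0.26 (SE, edgeR adjusted p = 0.973). Among ERK and JNK genes, MAP2K1, the ERK kinase, had 264 ± 22.4 against 197 ± 18.5 CPM with no overlap between the groups (edgeR adjusted p = 0.349), and the list sum was 0.08. Insulin, PI3K and AMPK genes summed to -0.19, with PRKAA1 at -0.13.

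None of the remaining list sums passed. Of these lists only glycolysis, smooth muscle, leukocyte and mitochondrially encoded genes had enough tested members for the set test. None of them passed it in the main fit. Interferon response genes summed to a log2 fold change of 0.24 with HERC5 at 0.17, and DNA replication genes to 0.20 with RFC4 at 0.35. Mitosis genes summed to -0.56 (edgeR adjusted p = 0.0861) with PRC1 at -0.48. The p53 targets summed to 0.03, with 88.4% of the reads on DDB2, and the DNA repair gene XPC was at 0.56. Wnt genes gave -0.08 with CTNNB1 at 0.13. Nuclear genes of oxidative phosphorylation gave -0.0024 with NDUFS3 at 0.0080. Glycolysis and hypoxia genes gave -0.31 (camera adjusted p = 0.0774, and 0.00589 to 0.0214 in 4 of the 8 fits without 1 library, where an estimated correlation gave adjusted p of 0.161 to 0.286), with PKM at 126 ± 75.1 against 229 ± 84.1 CPM and VEGFA at -0.60. Smooth muscle and pericyte markers gave 0.01, led by MYH11 at 0.01, with a median of 0.01 and a mean of -0.02; DES, at -0.74, belongs to this list too. Leukocyte markers gave -0.0037, with 74.4% of the reads on CORO1A and CD14 at 0.40. Tendon and cartilage markers gave -0.09 with CHAD at 0.53. Endothelial and epithelial markers had no tested member, with at most 7 and 8 reads per library.

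Mitochondrially encoded genes stood apart by the gene that led them. ND6, a subunit of respiratory complex I and the only mitochondrial protein gene encoded on the light strand, held 8.14% of all gene reads, the most of any gene. Its deposited FPKM was 40.5 to 65.5 times that of the next mitochondrial protein gene in each library. Reads on ND6 came to 92782 ± 9783 CPM in si-CPT1B and 80140 ± 8797 CPM in NC (log2 fold change 0.21 ± 0.10 SE, edgeR adjusted p = 0.419). The list did not pass the set test (camera adjusted p = 0.227). It passed upward with no filter (camera adjusted p = 0.0398), at a mean of at least 5 CPM (0.0182) and without si-CPT1B replicate 1 (0.0472), where an estimated correlation gave adjusted p of 0.314 to 0.424. With all 8 libraries and the filter its median log2 fold change was 0.04, which was -0.01 with library size alone and -0.09 when libraries were scaled to all reads.

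**Figure D3:**
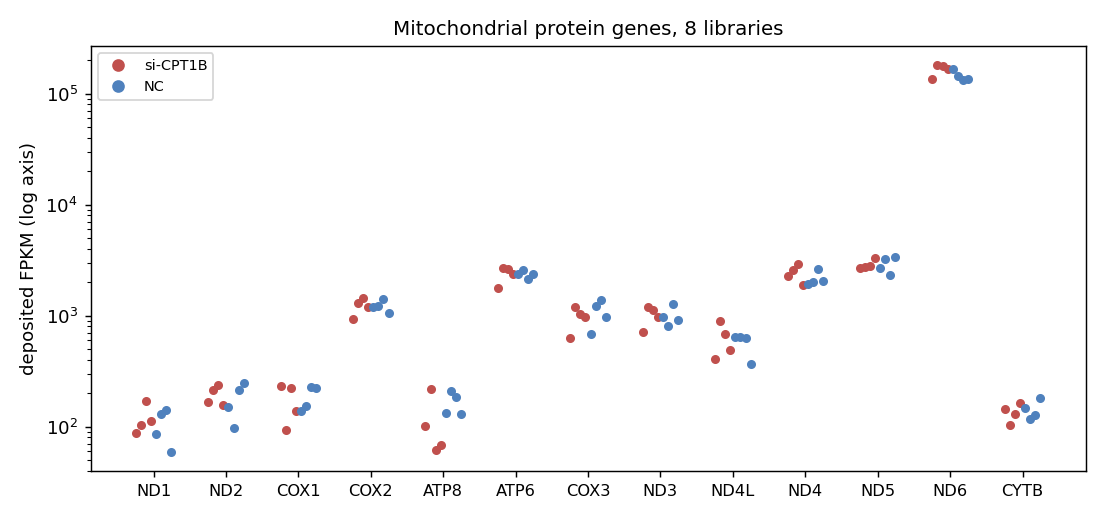
Deposited FPKM (log axis) of the 13 mitochondrial protein genes in order along the mitochondrial genome; each point is 1 of 8 libraries. ND6 lies above every other gene in all 8 libraries, by 40.5 times or more.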

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

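The test of reads not aligned was chosen after the result was seen; the counts of library splits were planned. Of 152 groups of 4 libraries examined, 6 held a library far from the other 3, where chance gives about 1 in 20.

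In si-CPT1B replicate 1, 3.86% of reads aligned to several places, against 3.24% to 3.31% in the other si-CPT1B libraries. CIDEB had 79.2 CPM in si-CPT1B replicate 4 and 55.8 to 59.3 CPM in the other 3. PDGFRA had 15.1 CPM in NC replicate 4 and 55.7 to 59.7 CPM in the other NC libraries. CHAD had 98.4 CPM in si-CPT1B replicate 3 and 200 to 210 CPM in the others. Fatty acid synthesis genes summed to 1450 CPM in si-CPT1B replicate 4 and 1840 to 1920 CPM in the others, and lipolysis genes to 266 CPM in si-CPT1B replicate 3 and 233 to 234 CPM in the others. Reads not aligned, which enter no comparison of genes, averaged 2.22% ± 1.02 in si-CPT1B libraries, above the NC range of 1.30% to 1.46% (SD, n = 4 each, two-sided exact permutation p = 0.143). The groups overlapped: si-CPT1B replicate 4 had 1.24%, below every NC library, while si-CPT1B replicate 1 had 3.66%.

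The number of lower genes was larger than other divisions of the libraries gave. Over the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 split, gave 4 genes or more in 1 direction. The highest other gave 1. That share, 1 of 35, is the smallest these splits can give, so chance cannot be excluded for the 4 lower genes either. The count of lower genes was 0 in 5 of the 8 fits without 1 library and 0 with the replicate number as a block. For the 1 higher gene, 3 splits gave as many, with a highest other of 1, and chance cannot be excluded. For the 3 lists, 8 splits gave as many and the highest other gave 5, so chance cannot be excluded for the lists.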

How the results depend on the processing

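The scaling to abundant mRNAs, the scaling to all reads and the list sums were chosen after seeing the data. At the depth of these libraries, 295349 to 352184 gene reads each, 2-fold changes were recovered in 57.8% of simulated genes. No other depth was simulated, so that share cannot be put down to depth. It was found with 200 of 1636 genes changed and 113 calls. Where as few genes pass as in the main fit, the adjustment asks for a smaller p and recovery would be lower. No alternative gave a value for CPT1B, which had 0 reads. The cause of the differences between settings was not tested.

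The main counts were 1 gene higher, 4 lower and 3 lists. DESeq2's size factors kept all 5 genes. Library size alone gave 7 lower. No filter gave 6 higher and 7 lower, and a mean of at least 5 CPM gave 2 higher and 5 lists; RIC3 lost its call in both (edgeR adjusted p = 0.271 and 0.137). DESeq2 gave 5 higher, and limma with quality weights 4 higher but 2 of the 4 lower genes lost (EIF4G2 at limma adjusted p = 0.0612, ENSCHIG00000011416 at 0.0822). By limma on log2 FPKM no gene passed, higher 0 and lower 0, with either pseudocount or without a filter, while 543, 561 and 556 genes had an unadjusted p under 0.05. A fold change of at least 1 on the log2 scale left 0 higher, and an adjusted p under 0.01 left 0 lower. Scaling to abundant mRNAs gave 108 higher and 2 lower (1.82% lower, against 80% with TMM) with a median of all genes of 0.70, and scaling to all reads gave 17 lower with a median of -0.13. Leaving out 1 library at a time gave 1 to 14 higher genes, 0 to 15 lower genes and 2 to 6 lists. The highest gene counts came without si-CPT1B replicate 1. For lists, 5 passed without si-CPT1B replicate 4 and 6 without NC replicate 1 or NC replicate 4. With an estimated correlation 0 lists passed and by fry 0, and 10 list sums passed without si-CPT1B replicate 1.

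With the replicate number as a block, 0 genes were higher and 0 lower (176 at an unadjusted p under 0.05 by edgeR), and 3 lists passed. Deviations of same-numbered libraries correlated at -0.05, 0.06, 0.04 and -0.12 across genes, against -0.117 to 0.204 for libraries of different numbers. These values gave no sign of pairing by number, but they cannot exclude it.

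Direction reversed for 24 settings of named genes and 4 of lists, none past the threshold in both. NDUFS3 was -0.042 with library size alone, -0.00733 by log2(FPKM + 1) with or without the filter, -0.00729 with a pseudocount of 0.1, -0.12 scaled to all reads and -0.093 to 0.17 with 1 library left out. ACADVL was -0.036 scaled to all reads. With 1 library left out ACADVL ranged from -0.24 to 0.33, LRP1 from -0.38 to 0.032, PRKAA1 from -0.48 to 0.12 and XPC from -0.12 to 0.92. Of the 24, 8 follow from the scaling to abundant mRNAs, which raised the median of all genes to 0.70: RIC3 was 0.21, ACOT8 0.40, LRP1 0.41, CEBPD 0.26, POLG 0.40, PRKAA1 0.49, PRC1 0.13 and HSP90B1 0.21. The list of PPAR regulators turned with adjusted p = 0.945 without a filter, 0.828 at 5 CPM and 0.976 on FPKM, and had 0.59 to 0.986 with 1 library left out.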

Other observations

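The tests of explanations in this part and the list sums without si-CPT1B replicate 1 were chosen after the results were seen, while leaving out each library in turn was planned. Without that library, which lay at -26.5 on a first principal component holding 32.3% of the variance and where the other 7 lay between -1.31 and 9.61, edgeR's quasi-likelihood test gave 14 genes higher and 15 lower. Reads on HDAC1, a histone deacetylase, rose 1.33-fold (edgeR adjusted p = 0.000815), those on ENPP1, an ectonucleotidase, 1.65-fold (edgeR adjusted p = 0.00315) and those on KHNYN 1.84-fold (edgeR adjusted p = 0.00315). Reads on the kinase gene STK16 fell to 0.68-fold (edgeR adjusted p = 0.000667), on COL1A2 to 0.657-fold (edgeR adjusted p = 0.0194), and on the splicing factor gene HNRNPA2B1 to 0.155-fold (edgeR adjusted p = 0.0194). CANX, EIF3A and PNN also fell, to 0.297-fold, 0.424-fold and 0.229-fold. None of these 9 genes passed in the main fit with all 8 libraries, where their adjusted p ranged from 0.056 to 0.266. COL1A2 did pass with all 8 libraries and no filter (edgeR adjusted p = 0.0167).

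The lists moved in the same comparison. The sum of mitochondrially encoded genes, 86.3% of it ND6 reads, rose by a log2 of 0.26 (edgeR adjusted p = 0.00854), while the other 12 differed by 0.10 (exact permutation p = 0.257). Summed reads of extracellular matrix genes fell by 0.37 (edgeR adjusted p = 0.00941), with ribosomal proteins at -0.58 (edgeR adjusted p = 0.00317) and peroxisomal oxidation genes at -0.64 (edgeR adjusted p = 0.0244). Preadipocyte genes (-0.29, edgeR adjusted p = 0.0468), mitosis genes (-0.59, 0.0437) and skeletal muscle markers (-0.40, 0.0157) also passed here. So did the cytokine, ATF4 and TGF-beta sums, which had passed with all 8 libraries. The set test with an estimated correlation gave an adjusted p of 0.347 for the mitochondrial, the extracellular matrix and the ribosomal protein list. Scaled to abundant mRNAs with all 8 libraries, the extracellular matrix sum was 0.05 and the median of all genes 0.70.

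Under 1% of the reads of these poly(A) libraries were counted on genes. Reads of genomic DNA would follow the length of a gene. Of the longest 10% of matched genes, 34.6% had 0 reads in all libraries, against 31.8% of all matched genes. Locus length stood in for exon length here, so that comparison alone does not decide. Reads of genomic DNA would also spread over all genes. Every library had at least 36575732 no-feature reads, yet 14311 of 27271 genes (52.5%) had 0 reads in every library. The 1636 tested genes held 94.1% of gene reads. For the genes counted, these values argue against genomic DNA as the source of most reads. A smaller share of such reads cannot be excluded. A dUTP library counted with the opposite strand setting is a candidate explanation: ND6, alone on the light strand, may then take reads of the other strand's transcript across its own locus while the other 12 lose theirs, and its FPKM was at least 40.5 times that of any other mitochondrial protein gene. Genes with a mean above 100 reads had another gene overlapping or within 1 kb 3 times as often as genes with 0 reads (78% against 26%, Fisher's exact p = 1.37e-53), as reads of neighbouring genes counted on the opposite strand would give, although gene-dense regions may also hold more expressed genes. RIC3 lies within 1 kb of TUB, HDAC1 of MARCKSL1, STK16 of GLB1L, HNRNPA2B1 of CBX3 and PNN of TRAPPC6B in RefSeq. KHNYN lies within 1 kb of CBLN3 and SDR39U1, and RPL31 of TBC1D8. Other named genes have such neighbours too, among them CEBPD (SPIDR), ACADVL (DVL2), ACOT8 (SNX21 and ZSWIM3), CIDEB (NOP9, LTB4R2 and LTB4R), MAP2K1 (SNAPC5 and LOC106502512) and CHAD (ACSF2). Differences of all these genes may belong to the neighbour. The strand setting is unknown and no biological explanation was tested for this pattern.

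Fewer reads on extracellular matrix and ribosomal protein genes in si-CPT1B is a hypothesis about abundant transcripts as much as about matrix. The ribosomal protein sum was lower too, with a 97.1% interval of its log2 difference from -1.89 to -0.187 (exact permutation p = 0.0286, and 0.0571 without si-CPT1B replicate 1). Its list was fixed in advance, but had been seen to be lower before the sum was chosen for this test. The sum therefore does not decide whether the matrix alone changed. Equal carry-over of sense reads from every transcript would lower the other mitochondrial genes too, if the reads counted on them were carried-over sense reads. The median log2 fold change of those genes was 0.029. Whether their reads were carried over is not known, so this does not decide. The data do not decide whether si-CPT1B replicate 1 alone carries the shift: the matrix sum without it had an exact permutation p of 0.0857, while camera with the preset correlation gave an adjusted p of 0.00181. A shift shared by abundant nuclear mRNAs, from less carry-over of their sense reads or from the knockdown itself, stays open: of a housekeeping list written after some members had been seen low, 18 of 19 tested genes were negative (median -0.68), and the ratio of matrix reads to housekeeping and ribosomal protein reads differed by a log2 of 0.05 (97.1% interval -0.133 to 0.212, exact permutation p = 0.429); the ratio of matrix to ribosomal protein reads, which replaced it after it was seen, differed by 0.23 (97.1% interval -0.0195 to 0.454), but these lists had been seen to be lower, so neither ratio decides.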
